A study of Mus musculus with 2 samples.

How the data were processed

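Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map acetylation of lysine 16 of histone H4 (H4K16ac) in brain tissue of mouse embryos at embryonic day 14.5. One library came from PHF20 knockout tissue and 1 from wild-type tissue, so each group held 1 sample and no replicate. No input or control-antibody library was analysed here. Per the labels' protocols, chromatin was cross-linked with formaldehyde, sonicated and precipitated with an antibody against H4K16ac bound to protein A magnetic beads. The series' design text names single-end sequencing on an Illumina Genome Analyzer II.

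Each deposited file held 1 row per placed read, with the base calls, chromosome, position, strand, mismatches and an alignment score. The authors placed the reads on mm9, per the submitters' processing notes. The aligner and its filters are not given in the sources used here. All reads were 36 bases long. The deposited alignment score ran from 4 to 119 in both files, and its median equalled its highest value. The read counts below were made from the deposited chromosome, position and strand, the base composition classes from the base calls, and the filtered alternatives from the mismatches and the score. The deposited reads had not been normalised and duplicates had been kept. The instrument fields of the files put both libraries in run 35, the knockout in lane 2 and the wild type in lane 1. Lane and genotype therefore coincide and cannot be told apart.

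Reads were reduced to 1 per chromosome, position of the 5' end and strand, and the 5' ends were counted in bins. The knockout file held 23023391 placed reads and 20422163 after this step (88.7%). The wild-type file held 22211873 and 19412238 (87.4%). Counts were scaled by each library's total of de-duplicated reads, or by its autosomal reads (19744902 and 18498639) where a value is given per autosomal read. Ratios are always knockout over wild type. Each ratio carries an exact Clopper-Pearson 95% interval computed from the combined count. Shares of reads carry exact binomial intervals. These intervals cover counting error only: reads carried no molecular identifiers, and the spread between embryos could not be measured with 1 library per genotype. For that reason no test across samples could be made between genotypes. The permutation tests below run over chromosomes or blocks of X within this 1 pair of libraries and describe these libraries only.

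The 10 kb bins were tested for size when they held at least 40 reads over both libraries. A bin was counted as higher or lower when its ratio reached 1.5-fold and its interval excluded 1. Binomial draws of the same combined counts at 1 common ratio gave the number that counting error alone produces. Enriched regions were found after thinning the knockout library to 19412238 reads. They were 1 kb bins above a Poisson p of 1e-05 against the larger of the genome mean and the mean of the surrounding 50 kb, with adjacent bins joined. Regions were called in each library and, for unbiased ratios, once in the pooled reads. Random splits of the pooled reads into 2 libraries of that depth gave the overlap expected from counting alone. Regions at 6 times the genome mean or more are called very high density regions. Base composition of 1 kb bins was taken from perfectly matching reads of both libraries, for bins with at least 8 such reads. A bin was called CpG-rich at a GC content of at least 50% and a CpG observed-over-expected value of at least 0.6.

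The calls were tested on simulated data made from the real combined counts of 232213 autosomal 10 kb bins. Of 200 bins changed 2-fold, 93.5% were recovered, and 98.5% of 200 bins changed 3-fold. Of the unchanged bins, 1.29% and 1.37% were called, which is more bins than the 200 changed, so counts of called bins are set beside binomial draws. In a simulation of 200000 flat 1 kb bins, 50.0% of 200 bins raised 3-fold and 91.0% of 200 raised 4-fold were called enriched.

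The gene table used here follows assembly GRCm38.p6, whereas the reads were placed on mm9. Its coordinates were therefore not used, and it served only for the chromosome of Phf20 and the number of protein-coding genes on each chromosome. Promoters, the fixed gene lists (NSL and MSL complexes, Hox genes, p53 targets, cell type markers and others) and the rule for named genes all need gene positions on mm9 and were not analysed here. The same ranking rule was applied to bins and regions instead: the 12 highest and the 12 lowest by the interval bound nearest to 1. Chromosomes, 10 kb bins and enriched regions were chosen before the data were examined, as were some of their alternatives; the closing section names those added later. Base composition classes, ratios in pooled regions, stretches of at least 3 bins of 100 kb beyond 1.15-fold, relations with gene density, mismatch shares and the scan for empty segments were added afterwards. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.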

Results

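PHF20 is a methyl-lysine reader and a subunit of the NSL complex, which contains the H4K16 acetyltransferase MOF (KAT8). The series asked whether deposition of H4K16ac is impaired when PHF20 is missing. Each library was scaled to its own reads, with no input or spike-in. The values below therefore compare the distribution of H4K16ac ChIP reads over the genome, background included. A global loss or gain would not show. H4K16ac ChIP-seq of brain from E14.5 mouse embryos was compared between 1 PHF20 knockout library of 20422163 de-duplicated reads and 1 wild-type library of 19412238. On the autosomes this gave 83.2 reads per 10 kb in the knockout and 78.0 in the wild type. Reads on opposite strands were most often separated by 155 bp in the knockout and 165 bp in the wild type. At that distance read pairs were 1.35 and 1.36 times as frequent as at 400 bp. GC content of perfectly matching reads was 41.4% in both libraries.

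Phf20 lies on chromosome 2. Its position on mm9 was not used here, so reads over the gene were not counted and the targeted locus gives no check of the genotype labels. On all of chromosome 2, no stretch without knockout reads held 20 or more wild-type reads, whereas 2 stretches without wild-type reads held that many knockout reads. Over all autosomes there were 15 such stretches without knockout reads and 64 without wild-type reads, 21 of the latter on chromosome 7. Most of these 21 lay between 60000001 and 69000000, where 6.82% of knockout and 18.1% of wild-type reads had mismatches. Some adjoin each other apart from a single position, so these numbers do not count separate deletions. How many such stretches counting alone would give was not computed. The knockout library was the deeper one, which favours stretches without wild-type reads. The wild-type library had 80.0 reads per 10 kb of chromosome 2, so deletions that would hold fewer than 20 reads were not detectable at this depth. A longer deletion could be missed too, since 1 stray knockout read within it splits the stretch.

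H4K16ac ChIP reads were spread over the 19 autosomes in nearly the same shares in both genotypes. The ratio of knockout to wild-type reads, per autosomal read, ran from 0.993 on chromosome 11 to 1.01 on chromosome 17. Chromosome X stood apart, with 3.11% of the knockout reads (95% interval 3.10 to 3.12%) and 4.55% of the wild-type reads (4.54 to 4.56%). Its ratio per autosomal read was 0.673 (0.671 to 0.675). Chromosome Y held 4489 knockout reads and 188 wild-type reads, a ratio of 22.4 per autosomal read (19.3 to 26.0). Scaled by all reads the Y ratio was 22.7, and it was 7.24 with duplicates kept and 59.0 with perfectly matching reads. The mitochondrial genome held 1057 and 1342 reads, a ratio of 0.738 (0.680 to 0.800). X and Y reads thus differed between the libraries in opposite directions, and this difference accompanies every genome-wide count below that includes them.

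**Figure D1:**
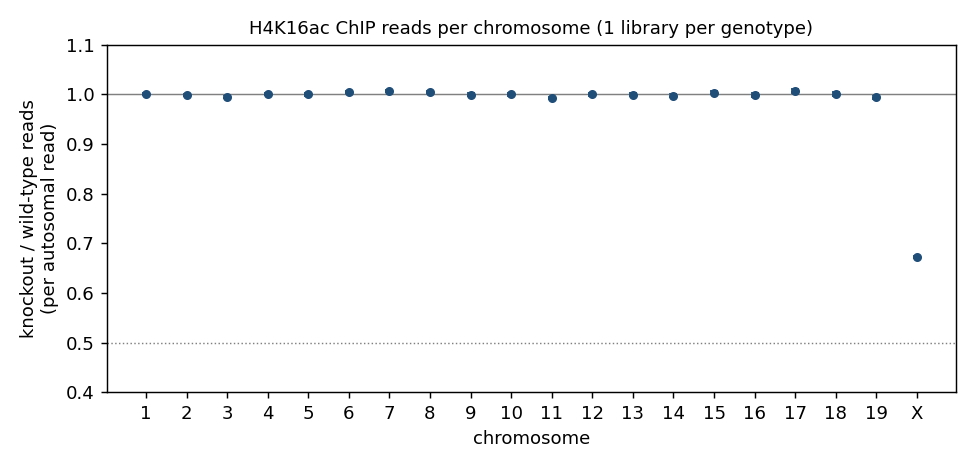
Knockout over wild-type H4K16ac reads per autosomal read (y axis) for each autosome and X (x axis); bars are exact 95% counting intervals, and lines mark ratios of 1 and 0.5. Autosomes lie between 0.993 and 1.01 and X lies at 0.673.

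At a resolution of 10 kb, the autosomal profile of ChIP reads was largely shared. Without an input library, background reads cannot be separated from H4K16ac in these bins. The autosomal regions called below from pooled reads held only 124589 of 19412238 knockout reads at equal depth. That calling set 1 kb bins against the surrounding 50 kb, so broad enrichment could go uncalled. How far the agreement between bins reflects H4K16ac therefore cannot be told. Of 232213 autosomal bins, 97.7% had a knockout to wild-type ratio within 1.5-fold. The 2894 bins counted as higher in the knockout and the 1682 counted as lower exceeded the 1919 and 1193 that binomial draws gave on average, and also their highest values of 2030 and 1284 over 100 draws. These counts use scaling by all reads, under which the ratios of whole autosomes lay between 1.01 and 1.02. Scaling by autosomal reads moved the split to 2357 higher and 2063 lower. The standard deviation of the log2 ratio was 0.25, against 0.24 from counting alone. Across autosomal bins the Spearman correlation of the read counts was 0.694, against 0.722 for a random division of the same reads. Bins are not independent replicates, and no p-value is attached to these figures. On X, 5847 of 13886 bins were lower in the knockout and 3 were higher, whereas draws at 1 common X ratio gave 5673 lower bins on average and at most 5776 over 20 draws.

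**Figure D2:**
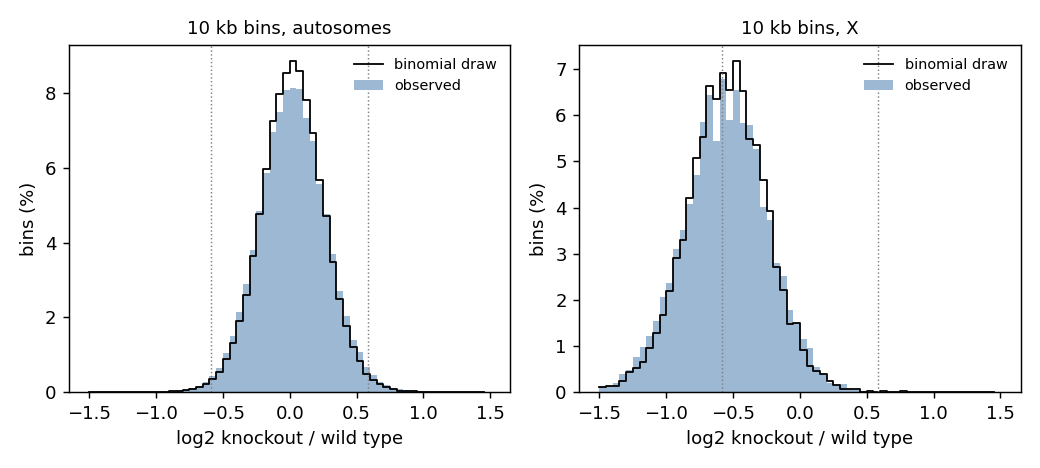
Share of 10 kb bins (y axis, percent) by log2 of knockout over wild-type reads (x axis) for autosomes and X; bars are observed bins, the line is 1 binomial draw at a common ratio, and dotted lines mark 1.5-fold. Autosomal ratios have a standard deviation of 0.25, and the X bins are centred at a log2 ratio of -0.55.

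The autosomal bins highest in the knockout lay in a few neighbourhoods of 2 chromosomes, whereas the lowest were spread over 6. The highest in the knockout was on chromosome 7 at 67840001 to 67850000, with 47 knockout reads and 1 wild-type read, a ratio of 44.7 whose interval starts at 7.64. Chromosome 7 at 60560001 to 60570000 had 83 and 4 reads, a ratio of 19.7 (7.42 to 74.1), and chromosome 8 at 15430001 to 15440000 had 39 and 2. All 12 highest bins lay on these chromosomes. The lowest included chromosome 11 at 71060001 to 71070000, with 5 knockout and 46 wild-type reads. They also included chromosome 7 at 38970001 to 38980000, with 154 knockout and 470 wild-type reads and a ratio of 0.311 (0.258 to 0.374). Among longer stretches, chromosome 17 from 30600001 to 31100000 had 8830 knockout and 6067 wild-type reads, a ratio per autosomal read of 1.36 (1.32 to 1.41) over 500 kb. Without an input library, a difference in DNA copy number cannot be separated from one in H4K16ac over such stretches. Chromosome 7 from 67800001 to 68100000 had a ratio of 1.58 (1.46 to 1.70), and chromosome 14 from 69800001 to 70100000 one of 0.743 (0.708 to 0.780). The named chromosome 7 bins at 60560001 and 67840001, higher in the knockout, lie in a stretch where 6.82% of knockout and 18.1% of wild-type reads had mismatches. Over all reads these shares were 11.0% and 16.5%. The chromosome 8 bins among the highest lie in stretches with 14.8% and 28.2% or 16.4% and 29.7%. All 12 highest bins thus lie where the wild-type excess of mismatches was larger than over all reads. The lowest bins were mixed. Those on chromosome 11 at 71060001 and chromosome 1 at 67020001 lie in stretches with 12.7% and 15.5%, and 22.5% and 13.1%. The chromosome 7 bin at 38970001 instead lies in one with more mismatches in the wild type (9.17% and 24.5%). Others lie in no stretch of differing shares. The chromosome 14 stretch lies in one with 20.1% and 18.9%. All coordinates are on mm9. Gene annotation of these positions was not used here.

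At equal depth, 1592 enriched regions covering 1801 kb were found in the knockout and 1631 covering 1819 kb in the wild type. Over 10 other thinning draws the knockout number ran from 1580 to 1628, and with duplicates kept the wild type had 2462. Of the knockout regions, 39.8% overlapped a wild-type region by at least 1 bp (95% interval 37.4 to 42.3%), and 39.3% of the wild-type regions overlapped a knockout region. Random splits of the pooled reads gave overlaps of 39.6 to 43.6% (mean 42.3%), and randomly placed regions 0.0942%. Both shares were near the lower end of the random splits. Over the other thinning draws the knockout share ran from 39.4 to 40.9%, so whether it lay inside their range depended on the draw, and the wild-type share lay slightly below it. Chromosomes with more protein-coding genes per Mb had more enriched regions per Mb, after leaving out very high density regions. Over 19 autosomes Pearson's r was 0.871 in the knockout and 0.857 in the wild type, and Spearman's rho 0.882 and 0.879. Each had a two-sided permutation p of 2e-05, the smallest that 100000 resamples can give, and an adjusted p of 3e-05 over 3 relations. Without chromosomes 7 and 11, r was 0.870 and 0.871. The read ratio between genotypes showed no such relation (r = 0.0311, p = 0.91, adjusted p = 0.91; rho = -0.011, p = 0.97, adjusted p = 0.97; r = 0.0171 without chromosomes 7 and 11, permutation tests). These are relations across chromosomes, which are not independent samples.

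**Figure D3:**
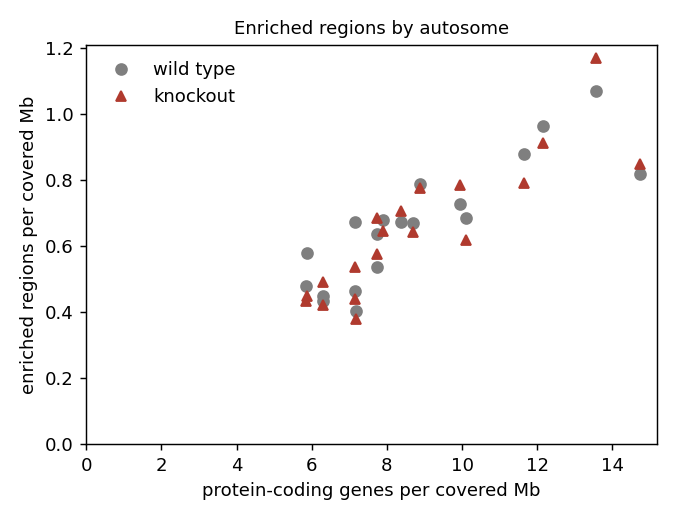
Enriched regions per covered Mb (y axis) against protein-coding genes per covered Mb (x axis) for the 19 autosomes, with circles for wild type and triangles for knockout. Regions became more frequent with gene density in both libraries (r = 0.871 in the knockout and 0.857 in the wild type).

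In regions called from the pooled reads at equal depth, the share of reads in autosomal regions differed by little between the libraries, and whether the counting interval included 1 depended on the scaling. The 3859 autosomal regions held 124589 knockout and 124539 wild-type reads, a ratio of 1.00 (0.993 to 1.01) at equal total reads and of 0.986 (0.978 to 0.994) per autosomal read. Leaving out 52 very high density regions brought the ratio per autosomal read to 0.995 (0.987 to 1.00). Of all these regions, 26.4% contained a CpG-rich bin, whereas 0.558% of all classed autosomal bins were CpG-rich. The 1014 CpG-rich regions below very high density had a ratio of 1.01 (0.992 to 1.02) per autosomal read. Of the 3361 regions with enough reads, 98 were higher and 85 lower in the knockout by 1.5-fold, where binomial draws gave 60.6 and 59.1 on average and at most 84 and 79. Per autosomal read the split was 86 higher and 89 lower.

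Ranked by the interval bound nearest to 1, the lowest of the regions below very high density was on chromosome 7 at 38973001 to 38976000, with 41 knockout and 187 wild-type reads. The highest was on chromosome 10 at 128259001 to 128260000, with 33 and 8 reads. The CpG-rich region of highest density below 6 times the genome mean was on chromosome 19 at 61275001 to 61276000, with 47 reads in each library. Another on chromosome 1 at 88421001 to 88423000 had 87 knockout and 94 wild-type reads. The very high density regions included chromosome 9 at 3000001 to 3001000 (41.2 times the genome mean) and chromosome 2 at 98502001 to 98508000 (38.5 times). Their combined ratio was 0.919 (0.898 to 0.941) per autosomal read, and none of the 52 reached 1.5-fold in either direction. Without an input library, high density can also come from sequence that is collapsed in the reference.

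CpG-rich bins, whose composition is typical of CpG island promoters, carried more ChIP reads than other classed bins. Relative to each library's own mean the excess was nearly the same in both libraries. Without an input library, this excess cannot be credited to H4K16ac rather than to background reads. The 11168 autosomal CpG-rich bins stood at 1.48 times the genome mean in the knockout and 1.49 times in the wild type. Classed bins had to hold at least 8 perfectly matching reads, which lifts every class: bins under 40% GC stood at 1.07 times the genome mean in both libraries, and GC-rich but CpG-poor bins at 1.11 times. The CpG-rich bins' knockout to wild-type ratio per autosomal read was 0.996 (0.989 to 1.00), and 0.983 (0.975 to 0.991) from perfectly matching reads. Autosomal bins with a GC content under 40% had a ratio of 1.00 (1.00 to 1.00). On X, by contrast, the ratio increased with GC content and was highest in CpG-rich bins. It was 0.667 (0.664 to 0.670) in bins with a GC content under 40%, 0.687 at 40 to 45%, 0.710 at 45 to 50%, 0.747 (0.731 to 0.764) in GC-rich but CpG-poor bins, and 0.876 (0.826 to 0.928) in the 248 CpG-rich bins. At a stricter CpG observed-over-expected value of 0.75 the last was 0.958, with an interval that reached 1 (0.880 to 1.04). The CpG-rich ratio exceeded that of the bins under 40% GC in 13 of 14 blocks of 10 Mb. The largest difference, 0.386, came from the last block, from 160000001, where the CpG-rich ratio was 1.07 from 591 reads. In that block the 1 Mb window from 166000001 had a ratio of 0.873 over all its reads. The values were not computed without this end of X. The other 3 of the 17 blocks of X held fewer than 40 reads in CpG-rich bins and were not used. The mean difference was 0.192 ± 0.0972 (SD over 14 blocks, exact two-sided sign-flip permutation test, p = 0.000244), where blocks of 1 chromosome in 1 pair of libraries are not independent replicates. In the 43 X regions called from the pooled reads the ratio per autosomal read was 1.01, with an interval that included 1 (2238 knockout and 2189 wild-type reads at equal depth), and in the 33 of them below very high density it was 0.821 (0.743 to 0.908).

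**Figure D4:**
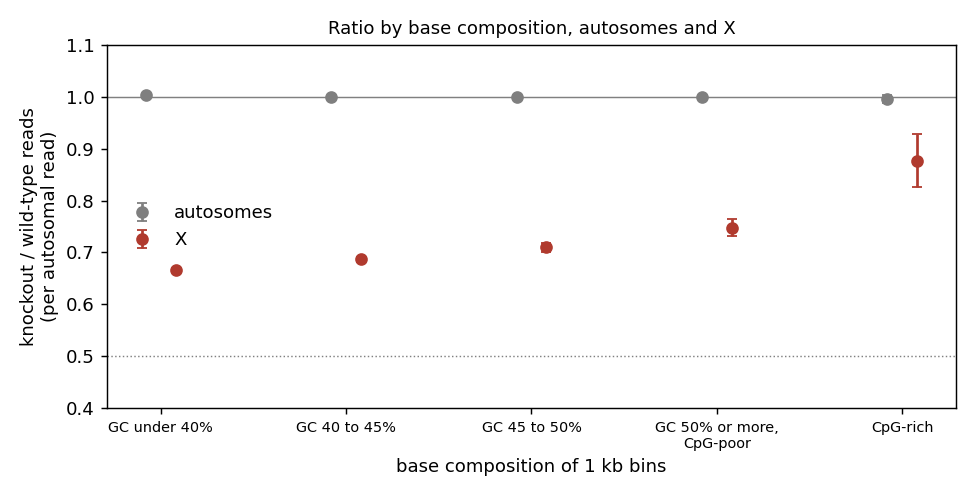
Knockout over wild-type reads per autosomal read (y axis) in 1 kb bins grouped by base composition (x axis), for autosomes in grey and X in red; bars are exact 95% counting intervals. Autosomal ratios lie close to 1 in every class, from 1.00 under 40% GC to 0.996 in CpG-rich bins, while X rises from 0.667 to 0.876.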

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

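The tests in this part were chosen after the results were seen. The mismatches recorded for each read served above only to select perfectly matching reads and to describe named stretches. Reads with at least 1 mismatch made up 11.0% of the knockout and 16.5% of the wild-type reads. After removal of the common ratio between the libraries, 102 autosomal windows of 1 Mb had a higher mismatch share in the knockout library and 146 a higher one in the wild type by over 2 percentage points, out of 2377 windows. A common ratio of perfectly matching shares, rather than a common difference, was chosen after the data were seen. These windows stand out because a difference between the libraries appears in data outside the main measurement. Long joined stretches included chromosome 15 from 16000001 to 27000000 (12.4% of knockout and 23.3% of wild-type reads) and chromosome 7 from 60000001 to 69000000 (6.82% and 18.1%). In the opposite direction, chromosome 1 from 65000001 to 70000000 had 22.5% in the knockout and 13.1% in the wild type. On chromosome 2, which holds Phf20, 2 of 177 windows deviated.

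More sequencing errors in 1 lane would shift all windows alike. The 248 deviating windows exceeded the highest of 100 binomial draws, 7, so lane errors are not the whole source. Of the deviating windows, 83.9% had a neighbour deviating the same way, against at most 17.3% after shuffling. Segments of another strain, carried by the knockout in some places and by the wild type in others, could give this pattern, although the labels give both samples the same strain. No variants were called, so the strain origin of any segment stays untested.

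Autosomal 10 kb bins beyond 1.5-fold were more frequent than counting error gives. In windows where 1 library had more mismatches than the common ratio gives, calls lower in that library were more frequent than in windows with like shares. The factor was 2.01 where this was the wild type (2.38% against 1.19% of bins) and 2.09 where it was the knockout (1.45% against 0.693%), although the chromosome 7 bin at 38970001 was lower in the knockout in a stretch with more wild-type mismatches. Strain segments may therefore account for the excess there. Windows with like shares also held an excess, with 3900 calls against at most 2892 in 100 draws. This does not exclude strain segments, since short ones need not move the share of a 1 Mb window by 2 percentage points. Such segments, copy number differences, unequal sampling of chromatin and differences in acetylation itself remain open for the calls in these windows. The same holds for the 500 kb of chromosome 17, and none was tested.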

How the results depend on the processing

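With 1 library per genotype no replicate could be left out. No paired analysis was possible because each group held 1 sample. The other settings foreseen for promoters beyond 1.5-fold, promoter enrichment, correlation and spread, gene list ratios and the Phf20 locus were not run, since gene positions on mm9 were not used here. A foreseen filter on scores above the median left no reads, so the highest score was used instead. Added after the data were seen were the filters on score and mismatches, autosomal scaling, 5' ends shifted by 75 bp, 10 kb bins with the deeper library thinned or without windows of differing mismatch shares, and every alternative for CpG-rich bins and region ratios. Under all alternatives run, 26 values stayed within 1.5 times the count or inside the counting interval and 17 did not. Some of the 26 could not change: an overlap rule leaves the number of regions as it was, and the wild-type library was never thinned. The X and Y ratios and the X CpG-rich ratio stayed on their side of 1. In 50 kb bins, 31 were higher and 13 lower in the knockout. Reads with the highest alignment score gave 5122 and 3365 autosomal 10 kb bins, and perfectly matching reads 4459 and 2798. No binomial draws were made for these settings, so their excess over counting error is not known. The mismatch filter also removed more of the wild-type reads (16.5%) than of the knockout reads (11.0%). The Y ratio became 7.24 with duplicates kept and 59.0 with perfectly matching reads. A stricter Poisson threshold left 471 knockout and 427 wild-type regions. With duplicates kept there were 2462 wild-type regions, and 34.3% of the knockout regions were shared. The CpG-rich ratio became 0.983 on autosomes with perfectly matching reads, and 0.958 on X at a CpG observed-over-expected value of 0.75. The autosomal region ratio was 1.01 (1.00 to 1.02, excluding 1) without very high density regions, but 0.975 (0.971 to 0.979) with duplicates kept and 0.986 (0.978 to 0.994) per autosomal read, so its side of 1 depends on the setting. The last is lower because the scaling leaves out X; for the others the cause was not tested. Depth limits the finding of 1 kb regions: bins raised 3-fold were called in 50.0% of simulated cases.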

Other observations

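In this part, the comparison of X bins by combined reads was fixed before its result was seen, and the other tests were chosen afterwards. With autosomal 10 kb bins put in 5 groups of equal size by combined reads, the knockout to wild-type ratio changed little, from 1.01 in the group with the fewest reads to 0.994 in the group with the most. On X it rose from 0.657 to 0.690 over such groups.

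The Y reads place the X difference beside a likely difference in sex between the samples, about which the labels used here say nothing. Autosomal CpG-rich bins had a ratio of 0.996 where a bias in base composition would need 1.31, and Y reads in the wild type stood at 0.0447 of the knockout level where male embryos mixed into that sample would need 0.514. Female embryos mixed into the knockout sample would by themselves give 1 ratio for all classes. They would leave the 0.876 (0.826 to 0.928) in CpG-rich bins against 0.667 under 40% GC unexplained. This difference between classes is the pattern being explained, so it is no separate test. A part in the overall level stays open. Reads per covered 10 kb of X, over those of autosomes, stood at 0.489 in the knockout and 0.727 in the wild type. The level that X would have in samples of known sex was not measured. A candidate explanation, as a hypothesis, is that 1 X chromosome of a female wild-type sample carries less H4K16ac, which predicts a higher ratio in X bins with more reads; the change on X beyond that on autosomes was 0.0469 by combined reads, which decides nothing because these include the knockout reads, and 0.0373 (0.0278 to 0.0467) in bins without CpG-rich sequence grouped by a random part of the wild-type reads that was left out of the ratio. In the latter, X went only from 0.665 (0.658 to 0.672) to 0.673 (0.668 to 0.678) and autosomes changed by -0.029, so most of the value comes from the autosomes. The hypothesis of less H4K16ac on 1 X chromosome stays open, as does an untested effect of PHF20 on X. Genotype and lane coincide, and the likely difference in sex would coincide with both.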
